A study of Homo sapiens with 16 samples.

How the data were processed

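RNA-seq libraries of U2OS cells (12, in 6 groups of 2) were analysed, grouped by the siRNA named in the sample labels: luciferase as the control, MRG15, MRGX, MRGBP, BRD8 or TIP60. Per the labels' protocols the RNA was poly(A)-selected and the siRNAs against MRG15, MRGX, MRGBP and TIP60 were pools. The one against BRD8 was given by a single catalogue number. The 4 chromatin immunoprecipitation samples of K562 cells, 1 per group, were not analysed here. Per the submitters' processing notes the tools included minimap2 2.17-r941, featureCounts of Subread 2.0.0, Bowtie2 2.1.6 and MACS2 2.0.10 with build hg19, with no role or order given. Whether strand was used in counting, the rule that selected the genes and the scaling of the library size are not given in the sources used here.

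The authors deposited values in CPM (counts scaled to library size) for each gene and library, in a table headed as holding significant differentially expressed genes. Of its 8813 rows, 5 repeated all 12 values of another row, under the same or a different name, and were removed, which left 8808 genes. 16 names retyped by spreadsheet software were kept in the tests and not named. Of the names 6721 matched a current symbol and 604 an older one in the reference annotation of GRCh38.p14, 7325 in all, and 1483 matched none. Builds differ, so no coordinates are printed. The authors' deposited table of transcripts held 20 marks of 0 or 1 per transcript, and 2 lists of gene names without values came with the deposited tables. Other sheets with the authors' group means and ratios, made from the same CPM values, were not used here.

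In each of the 12 libraries 100% of the CPM values were whole multiples of the value of 1 read (tolerance 0.01 reads), which gave effective library sizes of 57255783 to 110402095 reads and 20444328 to 42177876 reads in the listed genes. For siBRD8 replicate 1 and both siTIP60 libraries few values lay near the lowest steps, so their step rests on the differences of neighbouring values. CPM are not counts, so the main test ran on a log scale: limma 3.58.1 with an intensity trend in R 4.3.3 on log2(CPM + 1), with 6 group means fitted to all 12 libraries, without a replicate block and with no filter beyond the authors' own. Two-sided p-values were adjusted by Benjamini-Hochberg over the 8808 genes per comparison, with a threshold of 0.05. The residual degrees of freedom were 6. Leaving out a library left its group with 1, which was then assumed to vary like the other groups. The table holds selected genes alone, so the adjustment, set tests, correlations and overlaps are among them.

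Each knockdown was compared with siLuc, and siMRG15 with siMRGX and siMRGBP, siMRGBP with siTIP60, and siBRD8 with siTIP60 and siMRGBP. Named genes followed a rule. Against siLuc these were the 5 targets, the 8 largest positive and 8 largest negative changes and up to 4 members with the smallest adjusted p of each list discussed. Between knockdowns they were the targets and the 5 largest differences each way. The largest changes were taken among genes with a symbol, past the threshold, with a group mean of at least 5 CPM and both libraries on the same side of both compared libraries, without pseudogenes and genes of the sex chromosomes used to infer sex. A rule part for splicing events with the smallest p could not apply, since the transcript table holds marks alone, so FGFR2, TPM1, TPM2, PKM, PTBP2 and the targets were named. The 21 gene lists were TIP60 complex subunits, other MRG partner complexes, p53 targets, DNA replication, mitosis, homologous recombination, replication-independent and polyadenylated histones, cholesterol synthesis, integrated stress and unfolded protein response, interferon-stimulated genes, NF-kB targets, extracellular matrix and TGF-beta response, osteoblast genes, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, splicing regulators, autophagy and lysosome, oxidative phosphorylation, mitochondrially encoded genes, K562 erythroid and myeloid genes, and epithelial genes. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted by Benjamini-Hochberg over 75 tests. The groups, comparisons, lists, naming rule, tests and most alternatives were set before the data were examined.

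Similarity of knockdowns was measured by Pearson's correlation and covariance of changes across genes and by overlaps of calls. These stood beside 100 simulations of unchanged groups against a shared simulated control and 100 against the real siLuc libraries with their spread. The overlap of independent lists was given too. The main test was checked on simulated data for siTIP60 against siLuc with 200 of 8808 genes changed, where it recovered 10% of genes changed 1.2-fold, 74% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 10 unchanged genes called. The real table, with more genes changed, has a looser threshold, and at its unadjusted p the test recovered 54, 98, 100 and 100%. The spread between replicates exceeded counting noise in every group: chi-square per degree of freedom ran from 4.73 in siBRD8 and 8.03 in siMRGX to 27.9 in siTIP60 and 52.9 in siLuc, so no libraries were merged.

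Alternatives were a replicate block, pseudocounts of 0.5 and 5, filters on low CPM, median-of-ratios and TMM factors, only the compared groups in the fit, a minimum change of 1 on the log2 scale, no trend, each library left out, fry, Spearman's correlation and genes in place of transcripts. On the recovered reads, with the authors' scaling kept, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run as alternatives. They called 6142 and 5887 genes in siMRG15, 6073 and 5821 in siMRGX, 5674 and 5400 in siMRGBP, 4906 and 4622 in siBRD8 and 6954 and 6722 in siTIP60. Chosen after seeing the data were rescaling without 5 ribosomal RNA precursor genes, TMM for lists, the alternatives for single named genes, similarities with a different control library for each knockdown, the simulation with the siLuc spread, and set tests between knockdowns. Tables were handled in Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9.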

Results

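The MRG proteins MRG15 (gene MORF4L1) and MRGX (gene MORF4L2) are paralogous chromatin proteins found in several complexes, among them the TIP60 histone acetyltransferase complex and histone deacetylase complexes of the SIN3 type. Poly(A) RNA of U2OS cells, a human osteosarcoma line, was sequenced after transfection of small interfering RNAs (siRNAs) against MRG15, MRGX, MRGBP, BRD8 or TIP60 (gene KAT5), or against luciferase (siLuc) as the control. MRGBP and BRD8 are subunits of the TIP60 complex, and TIP60 is its acetyltransferase. Each of the 6 groups held 2 libraries, 12 in all. A further 4 chromatin immunoprecipitation samples of K562 cells, a chronic myeloid leukaemia line, were not analysed here. The effective library size recovered from the values ranged from 57255783 to 110402095 reads. The 8808 genes tested held 20444328 to 42177876 reads, 30.4 to 38.2% of a library.

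The gene table held only genes that the authors had selected as differentially expressed, so every count, overlap and set test below is among selected genes and says nothing of the genes left out. Changes are log2 differences of log2(CPM + 1), knockdown minus siLuc unless another pair is named, given ± SE with n = 2 libraries per group. Levels are mean CPM ± SD. A gene is said to rise or fall where the limma adjusted p was under 0.05, and log2 changes understate those of low genes. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between libraries, which may be technical. For each gene that spread was pooled over the 6 groups. Replicates differed most in siLuc by chi-square per degree of freedom (52.9), so p-values against siLuc may be too small. Unchanged groups simulated with the siLuc spread gave a mean of 406 calls per knockdown. These were counted at the unadjusted p where the real calls end. Each gene named among the largest changes lay on the same side of both libraries of the compared group in both libraries. This was not required of genes named from lists, such as HBA1 in siTIP60.

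Each siRNA lowered its own target. MORF4L1 fell from 322 ± 8.81 CPM in siLuc to 14.7 ± 1.44 CPM in siMRG15 (-4.36 ± 0.07; limma adjusted p = 5.08e-13), and MORF4L2 from 269 ± 40.7 CPM to 19.9 ± 0.576 CPM in siMRGX (-3.68 ± 0.09). MRGBP fell from 103 ± 16.8 CPM to 7.89 ± 0.104 CPM in siMRGBP (-3.54 ± 0.09), BRD8 from 76.8 ± 4.66 CPM to 18.6 ± 0.0235 CPM in siBRD8 (-1.99 ± 0.07) and KAT5 from 19.2 ± 0.659 CPM to 2.64 ± 0.228 CPM in siTIP60 (-2.47 ± 0.07). Targets also moved under siRNAs not directed at them. MORF4L2 fell in siMRG15 (-0.76 ± 0.09), siMRGBP (-0.49 ± 0.09), siBRD8 (-0.61 ± 0.09) and siTIP60 (-0.94 ± 0.09), whereas MORF4L1 in siMRGX differed from siLuc by less than the test could resolve (-0.04 ± 0.07; limma adjusted p = 0.639). MRGBP fell in siMRG15 (-0.58 ± 0.09), siBRD8 (-0.43 ± 0.09) and siTIP60 (-1.18 ± 0.09). BRD8 fell in siMRGBP (-0.68 ± 0.07) and siTIP60 (-0.69 ± 0.07), and MORF4L1 in siTIP60 (-0.66 ± 0.07). The smaller fall of MORF4L1 in siMRGBP (-0.18 ± 0.07) lost its call without siLuc replicate 2 (limma adjusted p = 0.107) or siMRGBP replicate 2 (limma adjusted p = 0.141), and under 3 other settings. KAT5 did not pass the test in siMRG15 (-0.13 ± 0.07), siMRGX (0.06 ± 0.07), siMRGBP (-0.14 ± 0.07) or siBRD8 (0.17 ± 0.07). KAT5 would have passed as higher in siMRGX with median-of-ratios (limma adjusted p = 0.0161) or TMM factors (limma adjusted p = 0.0101). With a pseudocount of 5 it would have passed as higher in siBRD8 (limma adjusted p = 0.0432). The pseudogene MORF4L1P1 shares sequence with MORF4L1 and fell with it in siMRG15 (-3.47 ± 0.10), so the split of reads between the pair is uncertain.

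**Figure D1:**
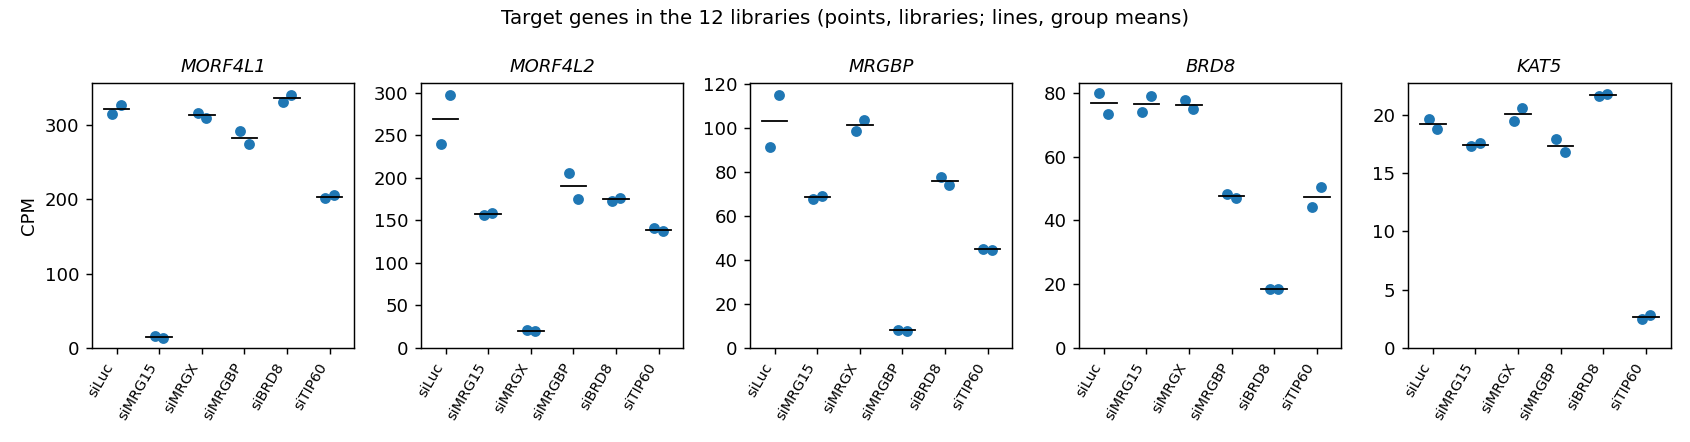
Level of the 5 targeted genes (panels; vertical axis in CPM, from 0) in the 6 groups (horizontal axis), with a point per library and a line at each group mean. Each gene is lowest under its own siRNA: MORF4L1 at 14.7 CPM in siMRG15, MORF4L2 at 19.9 CPM in siMRGX, MRGBP at 7.89 CPM in siMRGBP, BRD8 at 18.6 CPM in siBRD8 and KAT5 at 2.64 CPM in siTIP60.

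Gene lists were fixed before the data were examined: 21 lists, of which 15 had at least 5 measured members and were tested as sets in each knockdown (75 tests). With camera's preset correlation 26 tests passed the threshold, in each of which the median of the list lay beyond both control libraries in both knockdown libraries. With a correlation estimated from these libraries none passed in limma's camera (0 of 75, and 15 at an unadjusted p under 0.05), while 58 passed with fry, which asks only whether a list's genes move one way. The adjusted p of the estimated correlation stands beside each call. Unless a second number is given, the count of members adjusted over the list alone equalled that over all genes tested.

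The knockdown of MRG15 asked which transcripts depend on this subunit. The largest rises were in KREMEN1, a Dickkopf receptor of Wnt signalling, from 3.26 ± 0.0962 CPM to 28.3 ± 0.164 CPM (2.79 ± 0.11), and in RAB40B (2.52 ± 0.10), MXD4 (2.48 ± 0.09), SCN3B (2.38 ± 0.12), TXNIP (2.35 ± 0.11), SHC2 (2.34 ± 0.10), DOCK8 (2.30 ± 0.11) and PVRL4 (2.29 ± 0.07). MXD4 encodes a MAX partner that opposes MYC, TXNIP the thioredoxin-interacting protein, and SCN3B a sodium channel subunit. After MORF4L1 itself, the largest falls were in MAPK6, an atypical MAP kinase, from 266 ± 8.51 CPM to 39.4 ± 1.26 CPM (-2.73 ± 0.06), and in VTA1 (-2.59 ± 0.07), TNFAIP6 (-2.46 ± 0.15), OLFML3 (-2.37 ± 0.07), MOB3B (-2.37 ± 0.11), EFEMP1 (-2.30 ± 0.10) and PRLR (-2.29 ± 0.07). Of 17 measured p53 target genes 14 rose and 1 fell, with a median of 0.74 (camera adjusted p = 3.32e-05, adjusted p = 0.181 with an estimated correlation). Among them were FDXR (1.60 ± 0.06), SESN2 (1.42 ± 0.06), TP53I3 (1.41 ± 0.07) and BTG2 (1.16 ± 0.06).

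Cholesterol synthesis genes moved down in siMRG15. Of 14 measured members 12 fell and 2 rose (median -0.70; camera adjusted p = 9.82e-04, adjusted p = 0.272 with an estimated correlation). Members that fell included MSMO1 (-1.67 ± 0.09), IDI1 (-1.11 ± 0.07) and DHCR7 (-0.80 ± 0.07). Of 11 ribosome biogenesis and MYC target genes 8 fell and 0 rose (median -0.36; camera adjusted p = 0.0184, adjusted p = 0.272 with an estimated correlation). The ornithine decarboxylase gene ODC1 (-1.90 ± 0.09), of polyamine synthesis, fell, as did SRM (-0.84 ± 0.09), LDHA (-0.75 ± 0.09) and RRP12 (-0.38 ± 0.06). Of 17 extracellular matrix and TGF-beta response genes 11 fell and 3 rose (median -0.46; camera adjusted p = 0.0333, adjusted p = 0.509 with an estimated correlation). The secreted factor genes THBS1 (-2.08 ± 0.08) and CTGF (-1.74 ± 0.07) and the collagen cross-linking enzyme gene LOX (-1.62 ± 0.06) were lower and ACTA2 (1.32 ± 0.10), smooth muscle actin, was higher. Among 24 mitosis genes 14 fell and 1 rose (median -0.35; camera adjusted p = 0.0299, adjusted p = 0.568 with an estimated correlation). The cyclin genes CCNA2 (-0.82 ± 0.06) and CCNB1 (-0.78 ± 0.07), the anaphase activator gene CDC20 (-1.08 ± 0.07) and the mitotic kinase gene AURKA (-0.72 ± 0.06) fell. The call was lost without siMRG15 replicate 1 (camera adjusted p = 0.0711). Of 9 TIP60 complex subunit genes 6 fell and 1 rose (median -0.58; camera adjusted p = 0.0333, adjusted p = 0.191 with an estimated correlation). The target is one of them, and ACTL6A (-1.06 ± 0.06) and RUVBL1 (-0.65 ± 0.06) also fell. Integrated stress and unfolded protein response genes missed the threshold, with 10 of 14 lower (camera adjusted p = 0.0716), among them the chaperone gene HSPA5 (-1.75 ± 0.10). So did splicing regulators, with 7 of 11 lower (camera adjusted p = 0.0869), among them MBNL1 (-1.22 ± 0.07). Autophagy and lysosome genes missed it too, with 4 higher and 2 lower of 7, such as ULK1 (0.85 ± 0.09) and CTSL1 (-0.73 ± 0.08) (camera adjusted p = 0.451). All 5 measured epithelial genes fell (camera adjusted p = 0.0590). The keratin genes KRT18 (-0.85 ± 0.08) and KRT14 (-0.86 ± 0.13) were among them, and the set passed without siLuc replicate 2 (camera adjusted p = 0.0253). In all, 6100 of 8808 genes passed (2951 higher, 3149 lower), 449 of them at least 2-fold higher and 599 at least 2-fold lower.

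In siMRGX the most strongly raised transcript was TRAF1, an adaptor of tumour necrosis factor receptor signalling, from 2.38 ± 0.0188 CPM to 38.0 ± 1.17 CPM (3.53 ± 0.12). The heme oxygenase gene HMOX1 rose from 25.8 ± 4.34 CPM to 218 CPM (3.04 ± 0.12), followed by MMP3 (2.80 ± 0.16), IMPDH1 (2.40 ± 0.07), BIRC3 (2.21 ± 0.12), BCL7A (2.19 ± 0.09), MYCT1 (2.13 ± 0.14) and PXN (2.06 ± 0.07). After MORF4L2 itself, the insulin-like growth factor binding protein gene IGFBP5 fell most, from 363 ± 13.7 CPM to 35.0 ± 1.07 CPM (-3.34 ± 0.15), then NYNRIN (-2.93 ± 0.10), FAM70A (-2.84 ± 0.08), TNNT2 (-2.80 ± 0.18), EDN2 (-2.76 ± 0.11), DGKK (-2.72 ± 0.11) and PDGFRA (-2.62 ± 0.08). IMPDH1, BCL7A and PXN were higher and FAM70A and TNNT2 lower in all 5 knockdowns, so these changes were not particular to siMRGX. Cholesterol synthesis genes rose: 13 of 14 were higher and 0 lower (median 0.70; camera adjusted p = 1.83e-05, adjusted p = 0.181 with an estimated correlation). SREBF2, which encodes the transcription factor of this pathway, rose (1.08 ± 0.07), as did INSIG1 (0.90 ± 0.07) and SQLE (0.73 ± 0.06). Of 13 NF-kB target genes 11 rose and 1 fell (median 1.17; camera adjusted p = 1.49e-04, adjusted p = 0.181 with an estimated correlation). TRAF1, BIRC3 and SOD2 (1.17 ± 0.07) were among those raised, and TNFAIP2 (-1.02 ± 0.06) was the one lowered.

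Of 14 integrated stress and unfolded protein response genes 10 rose and 2 fell in siMRGX (median 0.51; camera adjusted p = 0.00269, adjusted p = 0.181 with an estimated correlation). Among those that rose were CHAC1 (1.56 ± 0.07), SLC7A11 (1.47 ± 0.10), ASNS (1.39 ± 0.08) and TRIB3 (0.76 ± 0.08), known targets of the transcription factor ATF4. Targets of ATF4 were not tested as a list of their own. Of 13 homologous recombination genes 7 rose and 1 fell (median 0.36; camera adjusted p = 0.0495, adjusted p = 0.568 with an estimated correlation). Those with the smallest p were XRCC2 (0.78 ± 0.09), RAD51AP1 (0.64 ± 0.07), XRCC3 (0.49 ± 0.07) and FANCA (0.38 ± 0.06). That call was lost without siLuc replicate 2 (camera adjusted p = 0.0725), siMRGX replicate 1 (0.0574) or siMRGX replicate 2 (0.053). Of 17 extracellular matrix and TGF-beta response genes 10 fell and 0 rose (median -0.44; camera adjusted p = 0.0299, adjusted p = 0.509 with an estimated correlation). The collagen gene COL3A1 (-1.95 ± 0.09) and LOX (-1.25 ± 0.06), BGN (-0.89 ± 0.10) and COL5A2 (-0.87 ± 0.10) fell. The call was lost with median-of-ratios factors (camera adjusted p = 0.0519), TMM factors (0.0538) or without siMRGX replicate 1 (0.0514). Ribosome biogenesis and MYC target genes, 7 of 11 higher with MYC itself at 1.25 ± 0.08, missed the threshold (camera adjusted p = 0.0537) and passed it with those factors (0.0371 and 0.0354). Mitosis genes (2 higher and 7 lower of 24, or 6 lower adjusted over the list alone; median -0.11) turned with either set of factors, to 7 higher and 2 lower. DNA replication genes (9 higher, 9 lower of 25) had a median of -0.10, a mean of 0.01 and medians of 0.07 and 0.08 with those factors. In all, 6008 genes passed, 2488 higher and 3520 lower, 373 and 733 of them at least 2-fold. Median-of-ratios factors moved the median of all genes by 0.11 and gave 3121 higher and 2886 lower, and TMM factors moved it by 0.12 and gave 3189 and 2817.

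In siMRGBP the smooth muscle actin gene ACTG2 rose most, from 1.38 ± 0.146 CPM to 23.4 ± 3.41 CPM (3.35 ± 0.11), and among the largest rises were also the actin-bundling gene LCP1 (3.18 ± 0.10) and the epiplakin gene EPPK1 (3.23 ± 0.15). The interferon-inducible GTPase gene GBP1 rose from 0.581 ± 0.103 CPM to 15.0 ± 0.990 CPM (3.34 ± 0.09), and ANKRD13A (3.22 ± 0.09), EGF (3.11 ± 0.09), SDPR (3.10 ± 0.11) and VCAN (2.80 ± 0.14) completed the largest rises. NDUFA4, a subunit of the mitochondrial respiratory chain, fell from 216 ± 80.3 CPM to 27.1 ± 5.48 CPM (-2.91 ± 0.19). The histone variant gene H2AFX fell from 268 ± 56.1 CPM to 45.5 ± 1.42 CPM (-2.52 ± 0.10), and THRA (-2.74 ± 0.10), LINC00473 (-2.56 ± 0.09), TNNT2 (-2.54 ± 0.18), SYT2 (-2.26 ± 0.08) and ACO1 (-2.26 ± 0.08) were also among the largest falls. TNNT2 and SYT2 were lower in all 5 knockdowns, so their falls were not particular to siMRGBP. Of 9 replication-independent and polyadenylated histone genes 8 fell and 1 rose (median -1.16; camera adjusted p = 0.00372, adjusted p = 0.191 with an estimated correlation). Of the 9, 4 (HIST1H2BK, HIST1H2BC, HIST1H2AC and HIST1H4C) belong to the histone clusters, so this list is not one of replication-independent genes alone. Besides H2AFX, HIST1H2AC (-1.49 ± 0.15), H1F0 (-1.19 ± 0.06) and H1FX (-1.16 ± 0.11) fell. Histone genes of multigene clusters share sequence, so their values are uncertain.

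DNA replication genes were lower in siMRGBP in 20 of 25 cases and higher in 2 (median -0.39; camera adjusted p = 3.38e-04, adjusted p = 0.414 with an estimated correlation). The helicase subunit genes CDC45 (-1.13 ± 0.07) and GINS4 (-0.72 ± 0.07) and the phosphatase gene CDC25A (-0.81 ± 0.07) fell. Mitosis genes were lower in 17 of 24 cases and higher in 0 (median -0.40; camera adjusted p = 3.38e-04, adjusted p = 0.414 with an estimated correlation). Examples were CDC20 (-0.73 ± 0.07), AURKA (-0.65 ± 0.06), CCNA2 (-0.59 ± 0.06) and CCNB2 (-0.59 ± 0.06). Of 13 NF-kB target genes 12 rose and 0 fell (median 0.50; camera adjusted p = 4.08e-04, adjusted p = 0.181 with an estimated correlation). TNFAIP3, an inhibitor of this pathway, rose (1.70 ± 0.13), as did BIRC3 (2.06 ± 0.12), IL1A (1.68 ± 0.13) and TRAF1 (1.61 ± 0.12). Homologous recombination genes, 8 lower and 1 higher of 13 with RAD51AP1 (-2.06 ± 0.07), missed the threshold (camera adjusted p = 0.0508). They passed it with TMM factors (0.0439) and without siLuc replicate 2 (0.0412) or siMRGBP replicate 2 (0.0426). Cholesterol synthesis genes (7 higher, 1 lower of 14; camera adjusted p = 0.0796) passed without siMRGBP replicate 1 (0.0473) and with fry (adjusted p = 7.50e-04). p53 target genes (10 higher, 3 lower of 17; camera adjusted p = 0.106) missed the threshold, with CDKN1A (1.21 ± 0.09), TNFRSF10B (1.09 ± 0.06) and PHLDA3 (-0.79 ± 0.06) among their members. TIP60 complex subunit genes, 6 lower and 2 higher of 9 with the target among them, missed it too (camera adjusted p = 0.118). In all, 5723 genes passed, 2824 higher and 2899 lower, 767 of them at least 2-fold. The small excess of lower genes turned at 2-fold (440 higher, 327 lower), with median-of-ratios factors (2937 higher, 2769 lower), a mean of at least 5 CPM (1861, 1791) or without siMRGBP replicate 1 (2673, 2520).

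The siBRD8 response was the smallest in number, with 4771 genes past the threshold (2491 higher, 2280 lower; 240 and 203 at least 2-fold). IMPDH1, an enzyme of guanine nucleotide synthesis, rose most, from 11.9 ± 0.463 CPM to 62.8 ± 0.458 CPM (2.30 ± 0.07), followed by CDC42SE2 (2.14 ± 0.07), MOB3B (2.12 ± 0.11), INPP5A (2.08 ± 0.08), NLRP10 (1.96 ± 0.12), WTIP (1.96 ± 0.08), DPF3 (1.91 ± 0.13) and SYNPO2L (1.88 ± 0.11). The long noncoding RNA LINC00473 fell most, from 7.36 ± 0.734 CPM to 0.488 ± 0.0393 CPM (-2.49 ± 0.09), and besides BRD8 itself MLLT11 (-1.97 ± 0.08), LAPTM5 (-1.95 ± 0.11), EDN2 (-1.94 ± 0.11), FAM70A (-1.92 ± 0.08), MOCS2 (-1.92 ± 0.09) and FAM167A (-1.84 ± 0.10) fell. IMPDH1, CDC42SE2, INPP5A and WTIP were higher and FAM70A lower in all 5 knockdowns, so these changes were not particular to siBRD8. Such a shared change cannot be told apart from a peculiarity of the siLuc cultures. Of 17 p53 target genes 13 over all genes tested, or 14 adjusted over the list alone, rose and 0 fell (median 0.62; camera adjusted p = 1.17e-05, adjusted p = 0.181 with an estimated correlation). These included the p53 ubiquitin ligase gene MDM2 (1.14 ± 0.08), the cell cycle inhibitor gene CDKN1A (1.04 ± 0.09) and SESN2 (1.43 ± 0.06) and RRM2B (0.79 ± 0.05). Of 14 integrated stress and unfolded protein response genes 9 rose and 1 fell (median 0.40; camera adjusted p = 0.00779, adjusted p = 0.181 with an estimated correlation). The amino acid metabolism genes ASNS (1.27 ± 0.08), PSAT1 (0.68 ± 0.07) and SLC7A11 (0.72 ± 0.10) and the glutathione-degrading enzyme gene CHAC1 (1.27 ± 0.07) rose. NF-kB target genes (8 higher, 2 lower of 13; camera adjusted p = 0.0622) and DNA replication genes (10 higher, 3 lower of 25; camera adjusted p = 0.0716) missed the threshold and passed it without siLuc replicate 1 (0.0428 and 0.0386). CCNE1, the cyclin E1 gene, rose by 1.41 ± 0.07, and TRAF1 (1.79 ± 0.12) and BIRC3 (1.85 ± 0.12) rose.

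The siTIP60 libraries showed the largest response, with 6940 genes past the threshold (3617 higher, 3323 lower; 1082 and 980 at least 2-fold). Among genes with a mean of at least 5 CPM the excess turned to lower genes (1932 higher, 2274 lower). The cytokine gene IL1A rose from 1.02 ± 0.0176 CPM to 49.7 ± 0.547 CPM (4.65 ± 0.13), and the phospholipase gene PLCH1 from 2.67 ± 0.0373 CPM to 69.3 ± 4.32 CPM (4.26 ± 0.11). Among the largest rises were also NLRP10 (4.11 ± 0.12), CSF2 (3.75 ± 0.11), KISS1 (3.59 ± 0.14), CST5 (3.58 ± 0.10), HHAT (3.47 ± 0.07) and SYNPO2L (3.37 ± 0.11). FAM111B fell from 86.7 ± 6.82 CPM to 5.98 ± 0.859 CPM (-3.65 ± 0.11), and CAPZA1 (-3.00 ± 0.08), HDGF (-2.93 ± 0.08) and NDUFA4 (-2.92 ± 0.19) were also among the largest falls. So were 4 histone cluster genes, HIST1H1A (-3.42 ± 0.26), HIST1H2AK (-3.26 ± 0.12), HIST1H2BN (-3.10 ± 0.07) and HIST1H3D (-3.09 ± 0.16), which share sequence with other members and are uncertain. HHAT was higher and HIST1H1A lower in all 5 knockdowns, so their directions were not particular to siTIP60. All 24 mitosis genes fell (median -1.58; camera adjusted p = 5.69e-10, adjusted p = 0.191 with an estimated correlation). The cyclin gene CCNA2 (-2.36 ± 0.06), CDC20 (-2.05 ± 0.07) and AURKA (-2.01 ± 0.06) and the kinesin gene KIF20A (-1.99 ± 0.07) fell. Of 25 DNA replication genes 24 fell and 0 rose (median -1.40; camera adjusted p = 2.10e-09, adjusted p = 0.191 with an estimated correlation). The nucleotide synthesis genes TYMS (-2.08 ± 0.07) and RRM2 (-1.88 ± 0.06) and the helicase subunit genes GINS2 (-1.69 ± 0.07) and MCM4 (-1.52 ± 0.06) fell. All 13 homologous recombination genes fell (median -0.94; camera adjusted p = 9.31e-05, adjusted p = 0.315 with an estimated correlation). The BRCA1 partner genes BRIP1 (-1.20 ± 0.09) and BARD1 (-1.18 ± 0.08) and RAD51AP1 (-1.73 ± 0.07) and FANCA (-1.06 ± 0.06) were among them.

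In siTIP60, 12 of 13 NF-kB target genes rose and 0 fell (median 1.36; camera adjusted p = 2.43e-04, adjusted p = 0.181 with an estimated correlation). Besides IL1A, the chemokine gene CCL20 (2.33 ± 0.11) and BIRC3 (3.03 ± 0.12) and TRAF1 (3.02 ± 0.12) rose. Of 14 integrated stress and unfolded protein response genes 12 rose and 2 fell (median 1.01; camera adjusted p = 0.00159, adjusted p = 0.181 with an estimated correlation). Examples were CHAC1 (2.40 ± 0.07), ASNS (2.19 ± 0.08), SLC7A11 (2.15 ± 0.10) and HERPUD1 (1.32 ± 0.06). Of 14 cholesterol synthesis genes 10 rose and 0 fell (median 0.38; camera adjusted p = 0.0333, adjusted p = 0.451 with an estimated correlation). Members that rose included INSIG1 (0.88 ± 0.07), HMGCS1 (0.73 ± 0.07) and SQLE (0.53 ± 0.06). Of 11 splicing regulators 9 fell and 1 rose (median -0.81; camera adjusted p = 0.0103, adjusted p = 0.181 with an estimated correlation). The splicing factor genes PTBP2 (-1.54 ± 0.06), MBNL1 (-1.40 ± 0.07), SRSF4 (-1.26 ± 0.06) and SRSF7 (-0.81 ± 0.05) fell. Of 9 replication-independent and polyadenylated histone genes, 4 of them cluster genes, 8 fell and 0 rose (median -0.93; camera adjusted p = 0.0184, adjusted p = 0.272 with an estimated correlation). H2AFX (-2.12 ± 0.10) fell most among those named, beside HIST1H2BC (-1.35 ± 0.12) and H1F0 (-0.93 ± 0.06). Of 9 TIP60 complex subunit genes, the target among them, 7 fell and 1 rose (median -0.69; camera adjusted p = 0.0184, adjusted p = 0.181 with an estimated correlation). Besides KAT5, MBTD1 (-1.05 ± 0.07) and MRGBP (-1.18 ± 0.09) fell. p53 target genes (9 higher, 4 lower of 17; camera adjusted p = 0.441) went both ways, with GDF15 (1.75 ± 0.09) and SESN2 (1.57 ± 0.06) higher and C12orf5 (-1.38 ± 0.07) and BTG2 (-1.32 ± 0.06) lower.

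Markers of other cell types and ribosomal RNA precursor transcripts moved in siTIP60 too. Of the epithelial genes, 3 of 5 fell and 1 rose in siMRGX (camera adjusted p = 0.575). In siTIP60 4 rose and 0 fell (camera adjusted p = 0.0716; 0.0412 without siLuc replicate 1), with the E-cadherin gene CDH1 (2.42 ± 0.08) and KRT5 (1.31 ± 0.13) and KRT18 (0.68 ± 0.08). Of 4 measured genes of the K562 erythroid and myeloid list 3 rose and 1 fell in siTIP60. PTPRC reached 5.97 and 3.35 CPM, and SPI1 (0.55 ± 0.18) and EPOR (-1.13 ± 0.09) were called too. HBA1 was at 6.74 CPM in replicate 1 and 0.0422 CPM in replicate 2, so its rise rests on replicate 1 alone. The 5 transcripts of ribosomal RNA precursor regions took 2.14 and 2.08% of the reads in the siTIP60 libraries, 0.94 and 0.43% in the siLuc libraries and 0.99 to 1.38% in the other 8.

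The remaining lists gave no set call in any knockdown or were too small to test. Interferon-stimulated genes went both ways in each knockdown, for example 4 higher and 4 lower of 12 in siMRGX (camera adjusted p = 0.953); IFIT1 (-1.88 ± 0.11) and IFI44L (-1.19 ± 0.09) fell there, and DDX58, which encodes the RNA sensor RIG-I, rose in siMRGBP (2.41 ± 0.08). All 4 measured genes of other MRG partner complexes fell in siMRGBP, among them C11orf30 (-0.93 ± 0.07), and 3 of them fell in siTIP60, with RBBP4 at -1.54 ± 0.06. Of 4 osteoblast genes 3 rose in siTIP60, with the alkaline phosphatase gene ALPL at 2.50 ± 0.10 and RUNX2 at 1.41 ± 0.06, and 3 fell in siMRG15, with SPP1 at -1.10 ± 0.12. Both measured oxidative phosphorylation genes fell in siMRGBP, where UQCRC2 was at -0.32 ± 0.07 beside NDUFA4. The single measured ribosomal protein gene, RPL30, rose in siMRG15 (0.64 ± 0.27) and siMRGX (0.95 ± 0.27). None of the 13 mitochondrially encoded genes was among the selected genes.

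**Figure D2:**
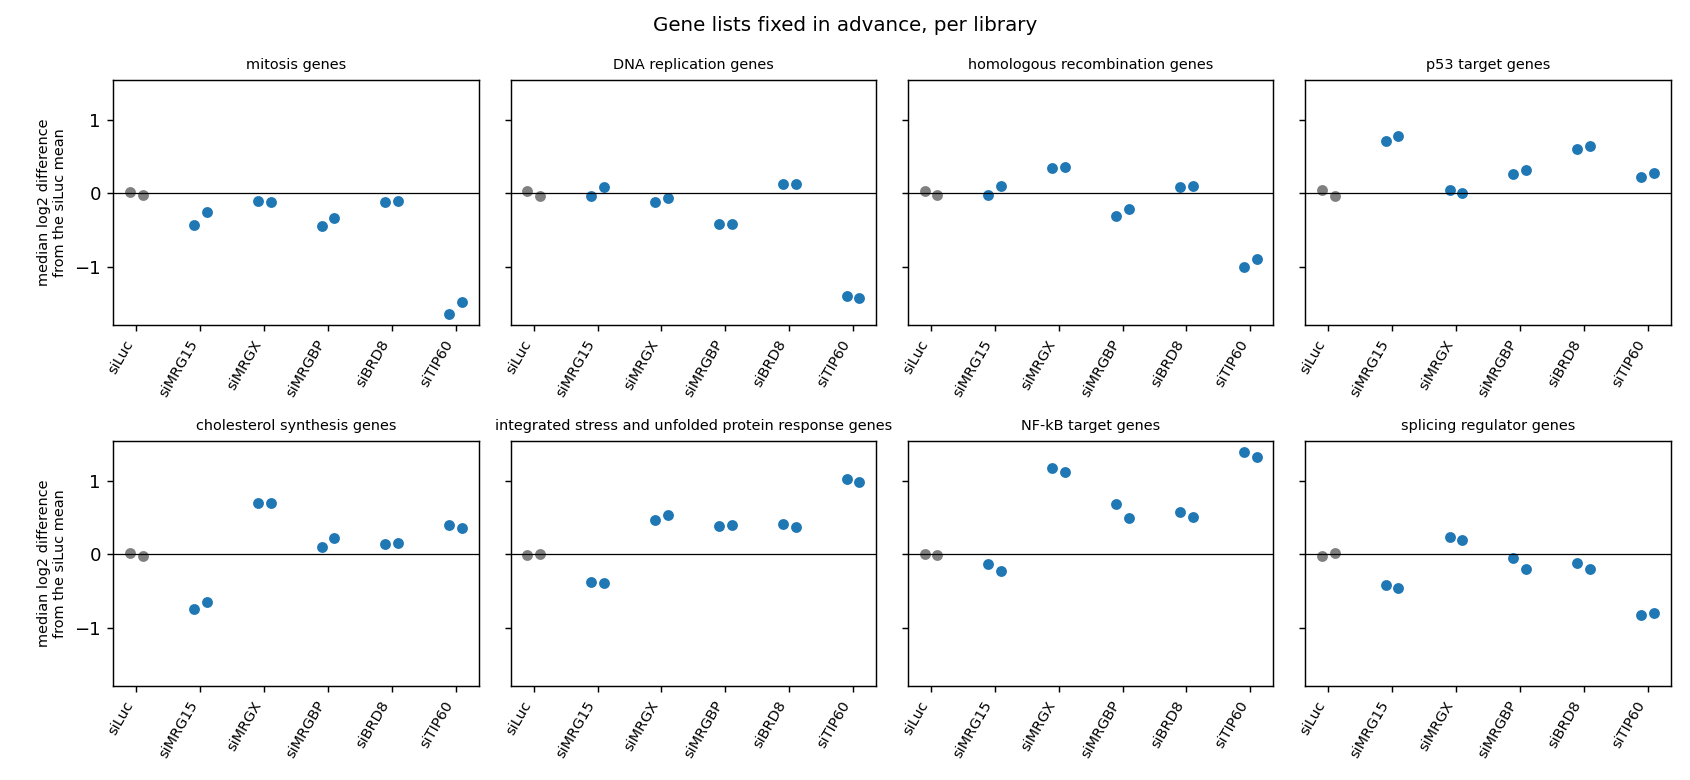
Median over the measured members of 8 gene lists (panels) of the log2(CPM + 1) difference from the siLuc mean (vertical axis), with a point per library in the 6 groups (horizontal axis; siLuc in grey). Mitosis genes lie at -1.64 and -1.48 in siTIP60, cholesterol synthesis genes at -0.74 and -0.66 in siMRG15 and 0.70 and 0.69 in siMRGX, and p53 target genes at 0.71 and 0.78 in siMRG15. With other library scalings mitosis and DNA replication genes in siMRGX change sign.

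The paralogs MRG15 and MRGX were compared directly to ask where their knockdowns differ. The matrix metalloproteinase gene MMP3 stood at 7.23 ± 0.614 CPM in siMRG15 and 178 ± 8.60 CPM in siMRGX (siMRG15 minus siMRGX, -4.45 ± 0.16). TRAF1 (-3.74 ± 0.12), MYCT1 (-3.18 ± 0.14), HMOX1 (-3.15 ± 0.12) and MORF4L1 (-4.32 ± 0.07) were also lower in siMRG15. Higher in siMRG15 were SHC2 (3.64 ± 0.10), KCNC1 (3.57 ± 0.11), C14orf132 (3.28 ± 0.08), VGF (3.27 ± 0.10) and LINC00473 (3.19 ± 0.09). KCNC1 encodes a potassium channel and VGF a neuropeptide precursor. All 14 cholesterol synthesis genes were lower in siMRG15 than in siMRGX (median -1.29; camera adjusted p = 2.09e-07, adjusted p = 0.163 with an estimated correlation). NF-kB target genes were lower in 12 of 13 cases (median -1.38; camera adjusted p = 2.36e-04, adjusted p = 0.163 with an estimated correlation). So were integrated stress and unfolded protein response genes in 12 of 14 (-0.99; camera adjusted p = 4.35e-04, adjusted p = 0.163 with an estimated correlation) and ribosome biogenesis and MYC target genes in 10 of 11 (-0.82; camera adjusted p = 0.00224, adjusted p = 0.163 with an estimated correlation). p53 target genes were higher in 16 of 17 cases (median 0.59; camera adjusted p = 0.00197, adjusted p = 0.163 with an estimated correlation). In all, 6559 genes differed, 3597 higher and 2962 lower in siMRG15, and the excess turned to 3072 and 3581 with TMM factors, which moved the median of all genes by -0.12. It also turned with median-of-ratios factors (3198, 3438) and a mean of at least 5 CPM (1903, 2238). The small difference in KAT5 (-0.19 ± 0.07) lost its call without siMRG15 replicate 1 (limma adjusted p = 0.0961), siMRG15 replicate 2 (0.0733) or siMRGX replicate 2 (0.162). The set tests between knockdowns, 75 over 5 pairs, were added after the data were examined. With the preset correlation 30 passed, each with medians apart in both libraries of one group and both of the other, and with an estimated correlation 0 passed in limma's camera, or 18 at an unadjusted p under 0.05.

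MRG15 was compared with MRGBP, which binds it within the TIP60 complex. The actin-bundling gene LCP1 stood at 3.76 ± 0.526 CPM in siMRG15 and 169 ± 26.3 CPM in siMRGBP (siMRG15 minus siMRGBP, -5.16 ± 0.10). Besides MORF4L1, ACTG2 (-3.70 ± 0.11), the transcription factor gene KLF2 (-3.67 ± 0.10) and the growth factor gene FGF1 (-3.67 ± 0.08) were lower in siMRG15, and LINC00473 (3.72 ± 0.09), MXD4 (3.27 ± 0.09), MRGBP (2.96 ± 0.09), SBK1 (2.92 ± 0.13) and TXNIP (2.84 ± 0.11) were higher. Cholesterol synthesis genes were lower in siMRG15 in 11 of 14 cases over all genes tested and higher in 1, or 2 adjusted over the list alone (median -0.90; camera adjusted p = 9.41e-04, adjusted p = 0.196 with an estimated correlation). DNA replication genes were higher in 19 of 25 cases (median 0.42; camera adjusted p = 0.0140, adjusted p = 0.530 with an estimated correlation). p53 target genes were higher in 13 of 17 cases (median 0.80; camera adjusted p = 0.0122, adjusted p = 0.196 with an estimated correlation). NF-kB target genes were lower in 11 of 13 cases and higher in 0 (median -1.02; camera adjusted p = 0.00197, adjusted p = 0.163 with an estimated correlation). In all, 6697 genes differed, 3455 higher and 3242 lower in siMRG15, which turned with a change of at least 1 on the log2 scale (672, 1054), a mean of at least 5 CPM (1929, 2136) or without siMRGBP replicate 1 (3112, 3114). MORF4L2, lower in siMRG15 by -0.27 ± 0.09, lost its call without siMRG15 replicate 1 (limma adjusted p = 0.0826), siMRG15 replicate 2 (0.0661) or siMRGBP replicate 1 (0.206).

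Between TIP60 complex subunits, siMRGBP against siTIP60 gave higher levels of ACTG2 (3.90 ± 0.11), the natriuretic peptide gene NPPB (3.74 ± 0.12), EGF (3.10 ± 0.09), PALM2 (2.92 ± 0.09) and CAPZA1 (2.91 ± 0.08) in siMRGBP. Lower in siMRGBP were PLCH1 (-4.19 ± 0.11), MMP9 (-4.09 ± 0.09), CST5 (-3.65 ± 0.10), NLRP10 (-3.50 ± 0.12) and SIGLEC15 (-3.47 ± 0.09). All 24 mitosis genes (median 1.18; camera adjusted p = 4.30e-10, adjusted p = 0.163 with an estimated correlation) and 24 of 25 DNA replication genes (median 0.87; camera adjusted p = 5.08e-08, adjusted p = 0.196 with an estimated correlation) were higher in siMRGBP than in siTIP60. Integrated stress and unfolded protein response genes were lower in 12 of 14 cases (median -0.69; camera adjusted p = 0.00197, adjusted p = 0.163 with an estimated correlation). In all, 6554 genes differed, 3067 higher and 3487 lower in siMRGBP, which turned with median-of-ratios factors (3311, 3239) or a mean of at least 5 CPM (2303, 1779).

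Against siTIP60, siBRD8 showed higher FAM111B (3.10 ± 0.11), TAF9B (3.07 ± 0.07), CAPZA1 (3.00 ± 0.08), E2F2 (2.65 ± 0.11) and KAT5 (2.64 ± 0.07), where E2F2 encodes a transcription factor of the cell cycle. KISS1 (-3.85 ± 0.14), the hedgehog-binding protein gene HHIP (-3.84 ± 0.10), the osteoprotegerin gene TNFRSF11B (-3.84 ± 0.08), IL1A (-3.78 ± 0.13) and SORBS2 (-3.50 ± 0.09) were lower in siBRD8. All 24 mitosis genes (median 1.53; camera adjusted p = 1.44e-10, adjusted p = 0.163 with an estimated correlation) and all 25 DNA replication genes (median 1.46; camera adjusted p = 4.51e-11, adjusted p = 0.163 with an estimated correlation) were higher in siBRD8. So were all 13 homologous recombination genes (median 1.14; camera adjusted p = 3.03e-05, adjusted p = 0.235 with an estimated correlation). In all, 6691 genes differed, 3129 higher and 3562 lower in siBRD8, which turned with a mean of at least 5 CPM (2318, 1841) or a change of at least 1 on the log2 scale (940, 864).

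Against siMRGBP, siBRD8 showed higher MOB3B (3.34 ± 0.11), MRGBP (3.11 ± 0.09), CXCL14 (2.80 ± 0.16), H2AFX (2.52 ± 0.10) and NDUFA4 (2.48 ± 0.19) and lower ACTG2 (-3.82 ± 0.11), EGF (-3.24 ± 0.09), EPPK1 (-3.19 ± 0.15), GBP1 (-3.16 ± 0.09) and STMN2 (-2.93 ± 0.09). All 25 DNA replication genes were higher in siBRD8 (median 0.55; camera adjusted p = 5.08e-08, adjusted p = 0.196 with an estimated correlation). So were all 9 replication-independent and polyadenylated histone genes, 4 of them cluster genes (median 0.88; camera adjusted p = 2.74e-04, adjusted p = 0.163 with an estimated correlation). In all, 5450 genes differed, 2897 higher and 2553 lower in siBRD8, which turned with median-of-ratios factors (2716, 2734) or a change of at least 1 on the log2 scale (331, 373). MORF4L1, higher in siBRD8 by 0.25 ± 0.07, lost its call without siBRD8 replicate 2 (limma adjusted p = 0.0561).

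**Figure D3:**
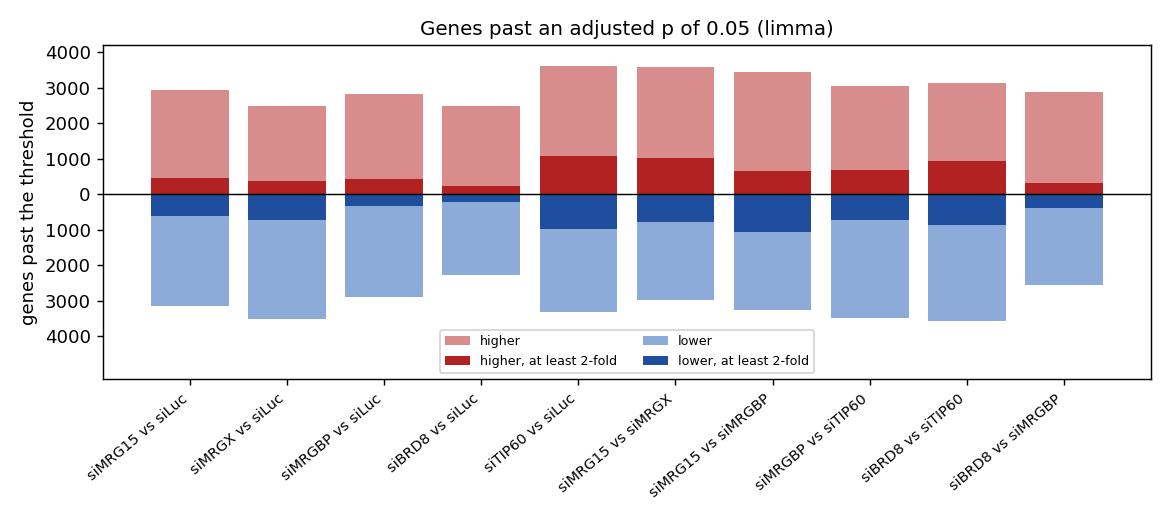
Number of genes past an adjusted p of 0.05 in limma (vertical axis; higher above 0, lower below 0, at least 2-fold in the darker shade) in the 10 comparisons (horizontal axis; first group minus second). Against siLuc the total runs from 4771 genes in siBRD8 to 6940 in siTIP60; in siMRGX the excess of lower genes (2488 higher, 3520 lower) is turned by median-of-ratios (3121, 2886) and TMM factors (3189, 2817).

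Across genes, the changes against siLuc correlated between all 10 pairs of knockdowns. Pearson's r was 0.53 for siMRGBP with siTIP60 and for siMRGX with siBRD8, 0.46 for siMRGBP with siBRD8, 0.42 for siMRGX with siMRGBP and 0.40 for siBRD8 with siTIP60. It was 0.37 for siMRG15 with siBRD8, 0.26 for siMRGX with siTIP60, 0.24 for the paralogs siMRG15 and siMRGX, 0.19 for siMRG15 with siTIP60 and 0.15 for siMRG15 with siMRGBP. Genes are not independent replicates, and all comparisons share the siLuc libraries. Unchanged groups simulated against 1 shared simulated control, with the spread pooled over groups, gave a mean r of about 0.50. Their mean covariance was no higher than 0.0055 in any pair. With the real siLuc libraries and their wider spread, run after the data were examined, unchanged groups gave a mean r of about 0.73. Their mean covariance was 0.0148, and the highest of any simulation was 0.0171. The observed covariances ran from 0.0596 for siMRG15 with siMRGBP to 0.278 for siMRGBP with siTIP60. For siMRGBP and siTIP60, 1891 genes were higher in both and 1826 lower in both, where independent lists would share 1160 and 1094. For siMRG15 and siMRGX, 1030 were higher and 1572 lower in both, where independent lists would share 834 and 1258, and 1731 went opposite ways. With a different control library for each knockdown of a pair (the mean of both assignments, run after the data were examined), r was lower in all 10 pairs, from 0.113 for siMRG15 with siMRGBP to 0.492 for siMRGBP with siTIP60. The covariances then ran from 0.0448 to 0.264 in the same pairs. This leaves 1 control library per knockdown, so overlaps were not counted that way and part of their excess may come from the shared controls.

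A total of 818 genes passed in the same direction in all 5 knockdowns, 405 higher and 413 lower. Of unchanged groups simulated 100 times with the spread of the siLuc libraries, at most 119 genes (mean 91.1) did so at the unadjusted p where the real calls end, and at most 1 at an adjusted p under 0.05. Independent lists would share 71.5, and separate real effects joined with the error of the shared controls were not simulated. By the size of their smallest change, IMPDH1 led the group: it stood at 11.9 ± 0.463 CPM in siLuc and between 44.9 CPM (siTIP60) and 71.0 CPM (siMRGBP) in the knockdowns. NF2, the merlin tumour suppressor gene, rose from 223 ± 2.80 CPM by at least 1.55 on the log2 scale, and HHAT (1.58 ± 0.07 in siBRD8), ADCY9, RPIA, INPP5A and the receptor kinase gene MET (1.93 ± 0.07 in siTIP60) were higher in all 5. The troponin gene TNNT2 (-1.55 ± 0.18 in siBRD8), SYT2 and the interferon-stimulated genes IFIT1 (-1.17 ± 0.11 in siMRG15) and IFI44L were lower in all 5. Genes of this group were named for the size of their smallest change or their list, after their values were seen. Without siLuc replicate 1 the count was 972, and without siLuc replicate 2 it was 734.

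The authors had listed 218 genes as lower and 215 as higher in both siBRD8 and siMRGBP. These lists were chosen on the same libraries and are not independent evidence of their own direction: of the 218 genes of the authors' deposited list, 214 fell in siMRGBP and 213 in siBRD8, and of the 215 genes, 210 rose in siMRGBP and 211 in siBRD8. In siMRGX 198 of the 218 fell and 4 rose, and 127 of the 215 rose and 51 fell. In siMRG15 121 of the 218 fell and 43 rose, and 112 of the 215 rose and 56 fell. In siTIP60 72 of the 218 rose and 52 fell, and 44 of the 215 rose and 75 fell. Knockdowns set against the controls that chose the lists lean the same way by chance. Unchanged groups with the spread of the siLuc libraries, held to the ratios the lists keep, gave at most 48 lower and 54 higher listed genes. In siMRGX at most 14 of the lower ones fell and 17 of the higher ones rose at the unadjusted p where the real calls end, so part of the lean may come from the shared controls. The lists left out genes past a bound in siTIP60: the lowest siTIP60 to siLuc ratio in the first of the authors' deposited lists was 0.703, and the second had a bound above.

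MRG15 has been linked to splice site choice, and the authors' deposited table of transcripts marks, for each comparison, which of 25895 transcripts of 11514 genes were listed as down or up. It gives no values, errors or p-values, and the rule behind its marks is not given in the sources used here. In the authors' deposited table, 3359 transcripts were down and 1889 up in siMRG15, 3652 and 2122 in siMRGX, 1510 and 2586 in siMRGBP, 1318 and 1396 in siBRD8, and 4642 and 5203 in siTIP60. Where the gene was also tested here, 81.0 to 93.3% of marked transcripts went with a call of the whole gene in the same direction, and 113 genes in siMRG15, 165 in siMRGX, 106 in siMRGBP, 56 in siBRD8 and 358 in siTIP60 had transcripts marked both ways in the authors' deposited table. The pyruvate kinase gene PKM had 2 of 5 transcripts marked down in siMRG15 and 2 marked up in siMRGX in the authors' deposited table. The tropomyosin gene TPM1 had 8 of 16 marked down in siMRGX, 4 down in siMRG15, 4 up in siMRGBP, and 3 down with 2 up in siTIP60. The splicing repressor gene PTBP2 had 3 of 5 transcripts marked up in siMRGBP, 4 down in siTIP60 and 2 down in siMRGX and siBRD8 each. FGFR2 had both of its 2 transcripts marked down in siMRGX and 1 in siTIP60, and TPM2 had 1 of 5 down in siMRG15 and 2 in siMRGX. Transcripts of the targets followed their siRNAs: 5 of 6 MORF4L1 transcripts were down in siMRG15, 7 of 8 MORF4L2 transcripts in siMRGX, 4 of 6 BRD8 transcripts in siBRD8 and 6 of 8 KAT5 transcripts in siTIP60. In the authors' deposited table siMRG15 and siMRGX shared 765 transcripts marked down and 580 marked up, where independent lists over all 25895 transcripts would share 474 and 155, and 114 were marked in opposite directions. By the same count siMRGX and siBRD8 shared 528 down and 674 up, where independent lists would share 186 and 114. For siMRG15 and siMRGBP these were 230 and 525, against 196 and 189. Relative to independent lists, the overlap of the paralogs was thus neither the largest nor the smallest. Transcripts of a gene are not independent and all knockdowns share the controls, so part of these overlaps may come from that. Across all 5 knockdowns 35 transcripts were marked down and 206 up.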

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

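Chosen only after the result was seen were the direct set tests between knockdowns, the rule that picked out the differences below, both tests of library scaling, the simulation of unchanged groups, and the test of unequal spread.

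A list was picked out where it was called in opposite directions against siLuc in the 2 knockdowns and the direct test passed (camera, Benjamini-Hochberg adjusted). Genes were taken only from those already named for the comparison. They had to be called in opposite directions against siLuc, by at least 1 on the log2 scale in both knockdowns, with the direct test passed (limma, Benjamini-Hochberg adjusted). Many more genes went opposite ways without meeting this rule, as 1731 were called so in siMRG15 and siMRGX. Cholesterol synthesis genes differed between siMRG15 and siMRGX with a camera adjusted p of 2.09e-07 (adjusted p = 0.163 with an estimated correlation), lower in 14 of 14 cases. In siMRG15 minus siMRGX, SHC2 differed by 3.64, KCNC1 by 3.57, C14orf132 by 3.28, LINC00473 by 3.19, MMP3 by -4.45 and MYCT1 by -3.18 on the log2 scale. In siMRG15 minus siMRGBP, LINC00473 differed by 3.72, SBK1 by 2.92, LCP1 by -5.16, KLF2 by -3.67 and FGF1 by -3.67. In siMRGBP minus siTIP60, NPPB differed by 3.74, PALM2 by 2.92 and MMP9 by -4.09. In siBRD8 minus siTIP60, HHIP differed by -3.84 and SORBS2 by -3.50, and in siBRD8 minus siMRGBP, MOB3B differed by 3.34.

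Cholesterol synthesis genes went opposite ways in siMRG15 (median -0.70) and siMRGX (0.70). With TMM factors, which moved the median of all genes by -0.12, the direct difference was -1.49. Over 4 scalings it stayed at -1.29 or lower with opposite signs against siLuc. The factors, 0.89 to 1.07 over all libraries, were too close to 1 to bring the difference near 0. That outcome was fixed in advance, so it does not weigh against scaling as a cause, and larger scaling errors were not tried. A single odd library is argued against, since with any of the 6 libraries left out the direct difference was -1.25 or lower and the signs stayed opposite. A difference between the responses to the paralogs may account for it, as a hypothesis. Off-target effects of an siRNA pool and differences between cultures stay open, since each knockdown used 1 reagent.

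Mitosis and DNA replication genes were lower in siTIP60 (medians -1.58 and -1.40). Over 4 scalings both medians stayed at -1.38 or lower, while the median of all genes lay between 0.02 and 0.06. The factors, 0.89 to 1.07 over all libraries, could not bring the medians near 0. That outcome was fixed in advance, so it does not weigh against library scaling as a cause, and larger scaling errors were not tried. A general fall of genes at their level was argued against: the lowest of 10000 random lists matched on mean expression had a median of -1.23. Slower growth of the siTIP60 cultures, as a response to TIP60 loss or to the reagent, may account for it, and density or cell cycle was not measured here. Reads of ribosomal RNA precursors, at 2.14 and 2.08% of the reads in siTIP60 against 0.94 and 0.43% in siLuc, stay open as a sign of a different library or RNA state.

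A set of 818 genes lay on the same side of siLuc in all 5 knockdowns. Unchanged groups with the spread of the siLuc libraries gave at most 119 such genes in 100 simulations at the unadjusted p where the real calls end, and 80.2% or more of the set stayed called without either control library, which argues against these as the whole cause. The simulation speaks only to chance values of the controls in otherwise unchanged groups. Separate real effects joined with the error of the shared controls were not simulated, nor was the authors' selection of the genes. A contribution of the shared controls of that kind therefore stays open. A peculiarity of the siLuc cultures cannot be told apart from a response shared by the knockdowns, since all 5 use the same control. A bound set before the result was seen counted against it, as siLuc had fewer such genes (818) than the median of the other groups taken as reference in turn (2068); that bound was wrong by design, because the counts of other groups include their own knockdown effects. The spread of the 5 changes relative to their mean was 0.44 with siLuc as reference and 0.32 to 0.47 for the other groups. It met the bound for an siLuc effect of equal size, which was no more than the highest other group. This decides nothing, because the values of other groups include their own knockdown effects. The genes were also picked as called on the same side in all 5, and a shared response of like size would meet the bound too.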

How the results depend on the processing

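Chosen only after results were seen were the alternatives for named genes, TMM factors for lists, rescaling without 5 ribosomal RNA precursor genes, a different control library for each knockdown, and a wider definition of the spread of similarities. The excess of higher or lower genes turned in 19 of 170 alternatives, in 8 of 10 comparisons (not siMRG15 or siBRD8 with siLuc): with median-of-ratios or TMM factors, a mean of at least 5 CPM, a minimum change of 1 on the log2 scale, or without siMRGBP replicate 1. No call of a target, named gene or list and no similarity changed sign. All 5 targets kept their call and direction in 40 of 40 alternatives, 151 of 170 alternative gene counts stayed within 1.5 times the main one, and over single named genes 4134 alternatives kept the call, 4 gained one and 12 lost it. A minimum change of 1 on the log2 scale left 1048 genes in siMRG15, 1106 in siMRGX, 767 in siMRGBP, 443 in siBRD8 and 2062 in siTIP60, since it adds a condition. Between knockdowns it left 1813 for siMRG15 against siMRGX, 1726 for siMRG15 against siMRGBP, 1417 for siMRGBP against siTIP60, 1804 for siBRD8 against siTIP60 and 704 for siBRD8 against siMRGBP. With a mean of at least 5 CPM, which tests 4915 genes in place of 8808, the same comparisons gave 3801, 3820, 3652, 4206 (siTIP60), 4141, 4065, 4082, 4159 and 3571, siBRD8 staying within 1.5 times. List calls, 26 in the main test, were 0 with an estimated correlation, 58 with fry and 24 to 29 with a library left out. Over single list tests 43 gained and 33 lost a call. The change of set test gave most of these: 32 gains came with fry in place of camera and 26 losses with the estimated correlation. The cause of the others was not tested. With Spearman's correlation similarity was 0.39 for siMRGX with siMRGBP, 0.485 for siMRGX with siBRD8 and 0.2073 for siMRGX with siTIP60. Without a control library, similarity ranged from 0.2241 to 0.2948 for siMRG15 with siMRGX, 0.1541 to 0.2142 with siMRGBP, 0.3539 to 0.4425 with siBRD8 and 0.1721 to 0.253 with siTIP60. For siMRGX it ranged from 0.4366 to 0.454 with siMRGBP, 0.5313 to 0.5674 with siBRD8 and 0.2458 to 0.301 with siTIP60. For siBRD8 it ranged from 0.4765 to 0.499 with siMRGBP and 0.381 to 0.4458 with siTIP60, the cause not tested. With a different control library for each, similarity was 0.1937 for siMRG15 with siMRGX, 0.3111 with siBRD8, 0.3725 for siMRGX with siMRGBP, 0.4605 with siBRD8 and 0.2235 with siTIP60. It was 0.3918 for siMRGBP with siBRD8, 0.492 with siTIP60 and 0.3474 for siBRD8 with siTIP60, the cause not tested. By the spread over knockdown libraries alone 40 of 60 alternative similarities moved, and by that over knockdown and control libraries, set after the first was seen, 20 of 60. Counted as genes in place of transcripts, siTIP60 had 2845 down and 3377 up, since a gene holds several transcripts. Stricter thresholds on splicing events were not run, because the table holds marks alone. Depth was not varied. In the simulation, with 200 of 8808 genes changed, 10% of genes changed 1.2-fold were recovered, or 54% at the unadjusted p where the real siTIP60 calls end.

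No label says what a replicate number shares, and same-numbered libraries deviated together with r from -0.47 to 0.18 over 15 pairs of groups, 3 of them over 0.1. With the replicate number as a block the counts were 6029 in siMRG15, 5907 in siMRGX, 5629 in siMRGBP, 4632 in siBRD8 and 6869 in siTIP60, and 6507, 6623, 6469, 6635 and 5386 for the comparisons between knockdowns. The block added 1 list call (homologous recombination in siMRGBP, camera adjusted p = 0.0464) and changed no other call of a list, target or named gene.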

Other observations

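The test of histone cluster genes in this part, and its bounds, were chosen only after the values were seen.

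Genes of the histone clusters, whose products package new DNA in S phase and most of whose transcripts lack poly(A) tails, were lower in several knockdowns. Of 40 measured genes 38 fell in siTIP60 (median -1.56) and 35 in siMRGBP (median -1.04), against 18 in siMRG15 (median -0.52), 19 in siMRGX (median -0.38) and 12 in siBRD8 (median -0.30). Of the 40, 4 (HIST1H2BK, HIST1H2BC, HIST1H2AC and HIST1H4C) also belong to the list of replication-independent and polyadenylated histones, and without them the medians were -1.58 in siTIP60, -1.03 in siMRGBP and -0.30 in siBRD8. The set of 40 gave an unadjusted camera p of 2.07e-09 in siTIP60 and 2.86e-10 in siMRGBP at the preset correlation, and 0.182 and 0.163 with an estimated one. The 2 that rose in siTIP60 were HIST2H2BC (1.14) and HIST2H2BD (0.72), at 1.55 and 1.02 CPM in siLuc. The genes share sequence and their RNA is partly lost in poly(A) selection, so single values are uncertain. The set medians likewise cover only the RNA kept by that selection, which limits the test of S phase below too.

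A candidate explanation is that fewer cells were in S phase. It asks for histone genes near the siLuc level wherever DNA replication genes are raised, and siBRD8, where their median was 0.13 and positive in both libraries, had a histone median of -0.2973, just short of the bound of -0.3 that would have counted against it. The bounds were first applied to any knockdown with a positive replication median, where siMRG15 (replication median 0.03, histone median -0.52) counted against the explanation. The rule was then narrowed, after that result was seen, because the siMRG15 replication genes went both ways, 8 rising and 9 falling. The explanation may hold in siTIP60 and siMRGBP, where replication genes also fell (medians -1.40 and -0.39), and remains open in the others.

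Of 9 measured TIP60 complex subunit genes 7 fell in siTIP60, among them MRGBP by 1.18 and MORF4L2 by 0.94 on the log2 scale, while RUVBL1 rose by 0.15 and YEATS4 was not called. The target KAT5 is one of the 7, so its fall was set by the siRNA. With KAT5 kept in, the set passed with camera's preset correlation (adjusted p = 0.0184) and not with an estimated one (adjusted p = 0.181). It was not tested without KAT5. In siBRD8 minus siTIP60 all 9 replication-independent and polyadenylated histone genes were higher (median 0.91; camera adjusted p = 0.00233, adjusted p = 0.163 with an estimated correlation), and splicing regulators were higher in 9 of 11 cases (median 0.92; camera adjusted p = 0.013, adjusted p = 0.163 with an estimated correlation). Interferon-stimulated genes did not share a direction in siTIP60, where 5 of 12 rose and 3 fell: DDX58 rose by 1.25 and IFIT1 fell by 1.93 on the log2 scale.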
